A study of Rattus norvegicus with 4 samples.

How the data were processed

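Gene expression was measured in scraped oxyntic mucosa of rats on Affymetrix RAE230A chips, 1 chip for a pool of 8 vehicle animals and 3 chips for pools of 2 octreotide LAR animals each. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit and labelled as biotin cRNA by in vitro transcription. The deposited table gives 1 linear signal intensity per probe set and chip. The algorithm behind these intensities and the scaling target are not given in the sources used here. No source used here records a scaling step, but the mean of the deposited intensities without the 2% at each end lay between 496.8 and 497.2 on all chips, as scaling every chip to 1 target would give. Such scaling sets the average level of every chip equal, so a change in total messenger RNA cannot be seen, and it leaves chip-specific curvature at low and high signal uncorrected. Per the experiment headers, all 4 chips shared 1 chip lot, 1 wash protocol and 1 hybridisation date. Each used its own fluidics module, and the vehicle group is a single chip. Groups were taken from the sample titles; the source name of the vehicle sample also mentions octreotide LAR, while its title gives vehicle; the treatment protocol and description are worded alike for all samples and do not tell them apart. Detection calls and control probe sets were not used here, so no probe set could be called absent and the planned ratio of 3' to 5' signal, a measure of RNA quality, was not computed.

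Signals were transformed as log2(signal + 16) with no further normalization, so a fold is on that scale and understates the change of dim genes. Probe sets whose mean over all 4 chips lay under the 40th percentile, equal to a signal of about 144.7, were left out, which left 9520. Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the spread on the level), 3 treated chips against 1 vehicle chip, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 2 residual degrees of freedom, the spread was moderated across probe sets with 11.5 prior degrees of freedom. The lone vehicle chip was assumed to vary like the treated chips, and it averages more animals than they do. Treated values are given as mean ± SD over 3 chips, and the vehicle value is a single measurement without error. Precision is limited by the number of chips. Probe sets were named through the platform annotation, updated by Entrez ID where the gene table of the GRCr8 assembly held it (12748 of 12783 matched): 12783 named 1 gene, 312 several and 2771 were unnamed here. No coordinates are given, since the deposited files name no genome build. A gene with several probe sets was represented by the one with the highest mean over all chips, which gave 7150 genes.

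The design, the alternatives, 37 gene lists and the rule for named genes were fixed before the data were examined. The text names, in each direction, the 12 genes with the largest difference past the threshold and the same direction on all treated chips, filled up by the smallest unadjusted p; a fixed set of marker genes; and, as a source of examples of which only some are printed, the 3 members of each list with the smallest p. Other list members named, and Ampd2, whose called probe set is not its brightest, were chosen after their values were seen. Lists with at least 4 measured genes (34) were tested with limma's camera, with a preset correlation of 0.01 between genes; camera with an estimated correlation and fry were alternatives. The lists of mucous neck cells, of B and plasma cells and of red blood cells had fewer measured genes and were not tested. Some lists share genes, such as Hdc, which is in the ECL, acid secretion and mast cell lists. Alternatives changed the pseudocount, the filter, the scaling, the moderation of the spread, the treatment of several probe sets and the set of treated chips. On simulated chips with the same levels and spread (20 runs, 200 of 9520 probe sets changed), the test recovered 42% of changes of 1 on the log2 scale, 77.6% of changes of 1.5 and 91.5% of changes of 2, and 4.92% of its calls were unchanged probe sets. These simulations assume that the vehicle chip has the spread of the treated chips, that the spread follows the fitted model, and that probe sets vary independently. They also hold 200 changes, more than the data gave calls, so the adjusted threshold was easier to pass. The shares recovered therefore need not hold for the data. Per the labels, each treated chip holds RNA of other animals, so its spread is that between pools of 2 animals plus the technical spread.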

Results

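The oxyntic mucosa, the acid-secreting lining of the gastric corpus, was scraped from female Sprague-Dawley rats at 21 days in a study of octreotide LAR, given at 5 mg per animal, and its vehicle. The labels word the scraped tissue as corpus gastric mucosa for the vehicle sample and as oxyntic mucosa for the treated samples. Octreotide is a long-lived analogue of somatostatin, the peptide that restrains gastrin, histamine and acid release in the stomach, and LAR is its slow-release depot form. One Affymetrix RAE230A chip was hybridised with RNA pooled from 8 vehicle animals, and 3 chips were each hybridised with RNA pooled from 2 octreotide LAR animals. The treated pools are called pools 1 to 3. The deposited table held linear signals for 15866 probe sets, of which 12783 named a single gene. The median signal was 225.9 on the vehicle chip, and on the treated chips it lay between 223.7 and 233.4. The 2%-trimmed mean lay between 496.8 and 497.2 on all 4 chips. Over the 9520 probe sets tested, the vehicle chip correlated with the treated chips at r = 0.9629 to 0.9679, and the treated chips correlated with each other at r = 0.9614 to 0.9685. The vehicle chip was therefore no farther from the treated chips than these were from each other over the whole profile.

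The comparison of octreotide LAR with vehicle asked which transcripts of the oxyntic mucosa differed after 21 days of a depot somatostatin analogue. Hdc, the histidine decarboxylase that makes histamine in enterochromaffin-like (ECL) cells, fell by 1.59 on the log2 scale and was the single probe set called lower. Of the 9520 probe sets tested, 9 were called higher, and 6 of them belong to genes of keratinising squamous epithelium: Lgals7, Loricrin, Krt1, Krt10, Sprr3 and Krtdap. The other 3 were Fabp2, a fatty acid binding protein of absorptive epithelium, Lgals4, a galectin of digestive epithelia, and a dim probe set of Ampd2, an AMP deaminase. A brighter Ampd2 probe set was tested and not called. The limma test thus called 10 probe sets at an adjusted p under 0.05, and 435 had an unadjusted p under 0.05, of which 272 were higher and 163 lower. A total of 31 probe sets lay at least 2-fold from the vehicle chip on every treated chip, 28 of them above it and 3, those of Hdc, Cym and Cela2a, below it. The filter acts on the mean of all 4 chips, and 21 of the 28 had a vehicle signal under its level; without it the split was 222 above and 120 below. When a treated chip was taken as the lone chip instead, the same count was 25 for pool 1, 20 for pool 2 and 8 for pool 3, again mostly with the lone chip low. Treated values lay on the same side of the vehicle value on all treated chips for 4660 probe sets, 48.95% of those tested, where chance gives 50% for a lone control. The test has 1 vehicle chip, so its spread comes from the treated chips alone and a peculiarity of the vehicle pool cannot be told from an effect of treatment. The count of calls was 53 without pool 1, 55 without pool 2 and 31 without pool 3, each including the 10 calls made with all chips, and it was 0 of 15866 without the filter on dim probe sets, where 776 had an unadjusted p under 0.05. It was 5 with quantile normalization or with centring on the 75th percentile, and 1 without a trend of the spread on the level. Fits without a treated pool keep the same vehicle chip and take the spread from fewer chips. Their calls rose although data were removed, so a pass in them, here and below, is no independent support.

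Genes of the ECL cell, the histamine-storing endocrine cell that relays the gastrin signal to parietal cells, were mostly lower: 7 of the 8 measured were lower in the mean, 6 of them on all treated chips. Sstr2 was the exception in the mean, at 0.11 on the log2 scale. It went both ways, with 0.12, 0.71 and -0.50 on pools 1, 2 and 3. A dimmer Sstr2 probe set, left out by the filter, was at -0.48. Ddc, an amine-forming decarboxylase, also went both ways. Hdc had a signal of 3537 on the vehicle chip and 1173 ± 132 (SD, n = 3) on the treated chips, a log2 difference of -1.59 with a 95% interval from -1.995 to -1.17 (limma adjusted p = 0.0027). The call was lost without the filter (limma adjusted p = 0.095) and without the trend (0.15); over all alternatives the adjusted p of Hdc ran from 1.72e-11 to 0.15. Slc18a2, the vesicular monoamine transporter that loads histamine into ECL granules, went from 2237 to 1011 ± 137 (SD, n = 3), a 2.21-fold difference that narrowly missed the threshold over all genes (limma adjusted p = 0.056; 0.00023, 1.68e-05 and 0.0044 without pool 1, 2 or 3, and up to 0.56 over all alternatives). A second, dimmer Slc18a2 probe set had 669.5 against 384.3 ± 130 (SD, n = 3) and was far from the threshold (limma adjusted p = 0.999). Chgb and Chga, the chromogranins of endocrine granules, had signals of 1607 and 7407 on the vehicle chip against 795.5 ± 29.1 and 4262 ± 383 (SD, n = 3) on the treated chips, with limma adjusted p of 0.11 and 0.15. Both passed without pool 1, 2 or 3 (limma adjusted p = 0.0016, 0.0047 and 0.046 for Chgb, 0.0011, 0.046 and 0.015 for Chga), and over all alternatives these ran up to 0.56 and 0.83. Of the 8 measured genes of the ECL list, 4 passed lower when adjusted over the list alone (Hdc, Slc18a2, Chgb and Chga) and 1 when adjusted over all genes (Hdc). The gastrin receptor Cckbr had 349.3 against 252.9 ± 69.8 (SD, n = 3) and did not pass. The median log2 difference of the list was -0.53, -0.76 and -0.74 on pools 1, 2 and 3. The list was called lower by limma's camera test with a preset correlation (adjusted p = 5.13e-10), and the call was lost with an estimated correlation (adjusted p = 0.46). The squamous list described below was higher on the same pools, at a median log2 difference of 1.97, 1.42 and 1.33. Its rise was largest on pool 1, where the fall of the ECL list median was smallest. Single ECL genes differed in this. On pools 1, 2 and 3, Hdc was at -1.70, -1.41 and -1.64 and Slc18a2 at -1.27, -0.93 and -1.23 on the log2 scale. Chgb was at -0.96, -0.99 and -1.06 and Chga at -0.81, -0.92 and -0.67.

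The wider list of the neuroendocrine secretory pathway had 13 of its 17 measured genes lower and was called lower by camera (median log2 difference -0.22, adjusted p = 1.98e-04; adjusted p = 0.68 with an estimated correlation). Chgb and Chga were its only members past the threshold adjusted over the list alone, and no member but these belongs to the ECL list. Pam, which amidates peptide hormones, had 3820 against 2874 ± 365 (SD, n = 3), and Ptprn, a granule membrane protein, had 446.7 against 265.2 ± 96.1 (SD, n = 3). Neither passed. Of the list of other gastric endocrine cells, 5 of 6 measured genes were lower in the mean, 2 of them on all treated chips, and none passed. These 2 were the peptides Cck, cholecystokinin, with 289.6 against 189.4 ± 17.6 (SD, n = 3), and Gal, galanin, with 230.1 against 161.1 ± 24.0 (SD, n = 3). Sst, the somatostatin of D cells, had 3909 against 3902 ± 323 (SD, n = 3), a log2 difference of -0.01 with a 95% interval from -0.36 to 0.35. Ghrl, the ghrelin of A-like cells, had 17694 against 17096 ± 2106 (SD, n = 3), a log2 difference of -0.06 with an interval from -0.41 to 0.30. That list was not called (camera adjusted p = 0.42).

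**Figure D1:**
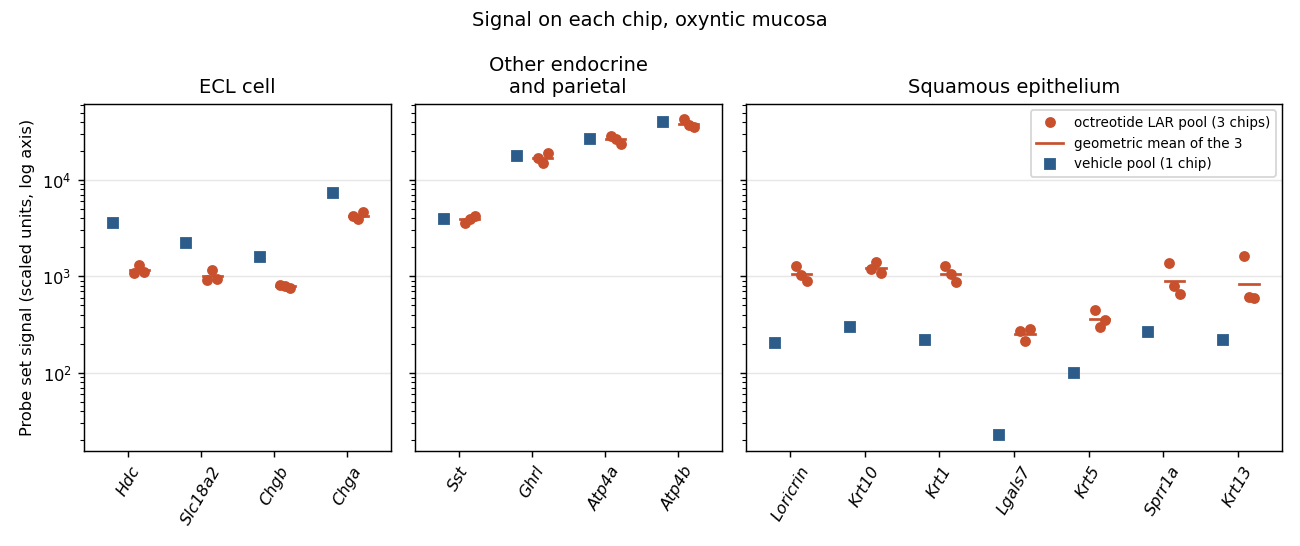
Probe set signal (scaled units, log axis) of ECL cell genes, of other endocrine and parietal genes and of squamous epithelium genes; squares are the 1 vehicle chip, circles the 3 octreotide LAR chips, and bars their geometric mean. Hdc lay at 3537 on the vehicle chip and at 1074.6 to 1323.2 on the treated chips, while Loricrin lay at 204.7 on the vehicle chip and at 890.3 to 1274.7 on the treated chips.

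Genes of keratinising squamous epithelium, which lines the rat forestomach next to the oxyntic mucosa, were higher on the treated chips. Loricrin, a cornified envelope protein, went from 204.7 to 1069 ± 194 (SD, n = 3), a 4.86-fold rise (limma adjusted p = 0.0012). Krt1 and Krt10, the paired keratins of the suprabasal layers, rose 4.58-fold and 3.99-fold (limma adjusted p = 0.0012 for both). Lgals7, a galectin of stratified epithelia, rose from 22.4 to 254.9 ± 37.3 (SD, n = 3; limma adjusted p = 0.0086); no fold is given, since the vehicle signal is so dim that the pseudocount largely sets it. Sprr3, another envelope protein, and Krtdap, a protein of differentiating keratinocytes, rose 3.55-fold and 2.97-fold (limma adjusted p = 0.029 and 0.047); a second Krtdap probe set was 0.95 higher on the log2 scale and was not called. All 12 measured genes of the squamous forestomach list were higher in the mean, 11 of them on all treated chips. Of these, 9 passed when adjusted over the list alone and 4 when adjusted over all genes. The 9 included Krt5, Krt14 and Krt15, keratins of the basal layer, with log2 differences of 1.69, 1.03 and 1.11. The vehicle signals of Krt5, Krt14, Krt15 and Sprr3 also lay under the filter level of 144.7, so the sizes of their differences depend on the pseudocount. The filter acts on the mean of all 4 chips, so genes this dim on the vehicle chip count as measured through their treated signals. The count of genes higher therefore leans on the filter. With the filter off, the list was called by camera with the preset correlation (adjusted p = 6.22e-15). Krt5 did not pass over all genes (limma adjusted p = 0.070) and passed without pool 1, 2 or 3 (0.016, 6.33e-05 and 0.0045; up to 0.83 over all alternatives). Krt13, a keratin of internal stratified epithelia, had 1632.8 on pool 1 and 610.4 and 594.5 on pools 2 and 3, against 218.6 on the vehicle chip. Sprr1a, an envelope protein, had 1379, 792 and 661.4 against 263.4 (limma adjusted p = 0.075 over all genes; 0.00015, 3.43e-09 and 3.38e-08 without pool 1, 2 or 3, and up to 0.84 over all alternatives). The list had the lowest camera p of all lists (median log2 difference 1.70, adjusted p = 4.36e-25; adjusted p = 0.46 with an estimated correlation). It was also called when pool 1 was taken as the lone chip in place of the vehicle chip.

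Genes of the surface and pit mucous cells, which line the lumen with mucus, were slightly higher. All 12 measured genes of that list were higher in the mean, 10 of them on every treated chip, but no single gene passed, either over all genes or adjusted over the list alone. The median log2 difference was 0.22, and the list was called higher by camera (adjusted p = 5.42e-04; adjusted p = 0.46 with an estimated correlation). Capn8, a calpain of gastric mucous cells, had 900 against 1412 ± 150 (SD, n = 3); a second Capn8 probe set had 485.9 against 500.03 ± 43.7 (SD, n = 3). Lgals3, a galectin, had 1815 against 2461 ± 216 (SD, n = 3). Muc5ac, the main surface mucin, had 21220 against 25326 ± 1583 (SD, n = 3). Gkn1 and Tff1, secreted pit cell proteins, differed by 0.18 and 0.08 on the log2 scale, neither past the threshold. Tff2, the trefoil peptide of mucous neck cells, had 6470 against 9646 ± 1436 (SD, n = 3), a log2 difference of 0.56 with a 95% interval from 0.19 to 0.94 that did not pass over all genes (limma adjusted p = 0.70; 0.040 without pool 1 and 0.040 to 0.9997 over all alternatives). Fabp2 rose from 533.2 to 1331 ± 218 (SD, n = 3) and Lgals4 from 3200 to 6593 ± 558 (SD, n = 3), 2.43-fold and 2.05-fold (limma adjusted p = 0.047 and 0.029). They were called under 6 and 7 of 11 alternatives, and the limma adjusted p of both ran up to 0.56 over all alternatives. The intestinal epithelium list that holds Fabp2 was not called with all chips (camera adjusted p = 0.14) and passed without pool 1 (adjusted p = 0.010; over all alternatives 0.0086 to 0.89). Squamous genes were higher on the same chips, as given above.

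Parietal cell genes, those of the acid-secreting cell, were not called as a list (median log2 difference -0.08, camera adjusted p = 0.38 with all chips, 0.027 without pool 1 and 0.027 to 0.93 over all alternatives). Atp4a and Atp4b, the subunits of the gastric proton pump, had 26692 and 39974 on the vehicle chip against 26482 ± 2554 and 38311 ± 3634 (SD, n = 3) on the treated chips. Their log2 differences were -0.02, with a 95% interval from -0.35 to 0.32, and -0.07, with an interval from -0.40 to 0.27. None of the 16 measured parietal genes passed; the smallest p was that of Kcnq1, a potassium channel of the secretory membrane, with 2855 against 1934 ± 432 (SD, n = 3). Next came its partner Kcne2, with 709.4 against 546.2 ± 36.4 (SD, n = 3), and Slc9a4, a sodium-proton exchanger, with 331.5 against 234.6 ± 58.1 (SD, n = 3). The oxidative phosphorylation list, whose genes are abundant in parietal cells, had 43 of 59 genes lower and was not called (camera adjusted p = 0.076 with all chips, 0.00033 without pool 1 and 0.00033 to 0.93 over all alternatives).

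Chief cell genes, which encode the digestive zymogens, differed among themselves. Cym, the milk-clotting protease chymosin, had 19071 on the vehicle chip against 3952.1, 8203.8 and 7560.9 on the treated chips, a 3.04-fold lower mean (limma adjusted p = 0.070 over all genes, 0.0010 adjusted over the list alone). It passed over all genes without pool 1, 2 or 3 (limma adjusted p = 2.02e-10, 2.94e-15 and 3.96e-12), and over all alternatives its adjusted p ran from 2.94e-15 to 0.9998. Those fits without a pool keep the same vehicle chip and rest on fewer treated chips, so their smaller p is no firmer evidence. Cym was the only one of 10 measured chief cell genes past the threshold adjusted over the list alone. Pgc, a pepsinogen, had 56281 against 55236 ± 6839 (SD, n = 3), and Cblif, the intrinsic factor that chief cells make in the rat, had 21273 against 19685 ± 849 (SD, n = 3). The list was not called with all chips (median log2 difference -0.11, camera adjusted p = 0.23), but passed without pool 2 (adjusted p = 0.00089) and without pool 3 (adjusted p = 0.00979); over all alternatives it ran from 0.00089 to 0.93. Enzymes best known from the exocrine pancreas were lower too. Cela2a, Cel and Cpa1 were 2.67-fold, 2.64-fold and 2.61-fold lower; none passed over all genes (limma adjusted p = 0.17, 0.17 and 0.46), and all 3 passed adjusted over the pancreatic acinar list alone. Over all genes they passed whichever treated pool was left out (limma adjusted p without pools 1, 2 and 3 of 0.0044, 0.00072 and 0.047 for Cela2a, 0.0032, 0.0056 and 0.0011 for Cel, and 0.044, 0.0069 and 0.0022 for Cpa1), and over all alternatives the adjusted p reached 0.84, 0.84 and 0.95. Clps and Pla2g1b, of the same list, had mean signals of 45633 ± 5485 and 55377 ± 7494 (SD, n = 3) on the treated chips against 48789 and 54590 on the vehicle chip. The list was called lower by camera (median log2 difference -0.26, adjusted p = 8.17e-05; adjusted p = 0.46 with an estimated correlation), and not when dim probe sets were kept (adjusted p = 0.15; over all alternatives 2.05e-06 to 0.46). The squamous list was higher on the same chips, at a median log2 difference of 1.97, 1.42 and 1.33 on pools 1, 2 and 3. That of the acinar list was -0.61, -0.27 and -0.56.

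Transcripts of the somatostatin receptors named here were dim. Sstr2, the receptor that octreotide binds most tightly, had 203.9 against 235.0 ± 102 (SD, n = 3). Sstr3 had 195.4 against 188.6 ± 4.75 (SD, n = 3), and neither passed the threshold. The probe sets of Sstr1 and Sstr5 lay under the level required for testing. The list of somatostatin receptors and their coupling was not called (camera adjusted p = 0.91), nor was the list of acid secretion control (adjusted p = 0.42), in which Hdc alone passed. The growth hormone and IGF axis, which somatostatin analogues restrain systemically, was not called (adjusted p = 0.42). Igf1 had 843.6 against 732.1 ± 177 (SD, n = 3), and Igfbp2, an IGF binding protein, had 3804 against 2680 ± 488 (SD, n = 3); neither passed. Lists of the EGF family and gastric growth factors, cell cycle and apoptosis were not called (camera adjusted p = 0.69, 0.59 and 0.95). Mki67, the Ki-67 proliferation antigen, had 189.1 against 450.0 ± 126 (SD, n = 3), 2.22-fold higher, but did not pass (limma adjusted p = 0.44; 0.0048 without pool 2 and 0.0048 to 0.95 over all alternatives). Other cell cycle genes went both ways: Kif20a, a mitotic kinesin, was 1.02 lower and Mcm6, a replication helicase subunit, 0.60 higher on the log2 scale, without passing.

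Ribosomal protein genes were the last list called. Of 26 measured, 23 were higher in the mean and none passed singly, over all genes or adjusted over the list alone; Rpl4 was 0.38 higher on the log2 scale. The median log2 difference of the list was 0.24, 0.13 and 0.10 on pools 1, 2 and 3, where that of the squamous list was 1.97, 1.42 and 1.33. Over the mean differences the ribosomal median was 0.17 (camera adjusted p = 5.42e-04; adjusted p = 0.83 with an estimated correlation), and the list was also called when pool 1 was taken as the lone chip. In all, 6 of 34 lists were called with the preset correlation and none with the estimated correlation or with the fry rotation test, where 3 and 4 lists had an unadjusted p under 0.05. With pool 1 as the lone chip 6 lists were called, those of ribosomal proteins, squamous forestomach, parietal cell, chief cell, oxidative phosphorylation and smooth muscle. With pools 2 and 3, 2 lists each were called. The metabolic and stress lists were not called: fatty acid oxidation and fasting (adjusted p = 0.42), lipid and cholesterol synthesis (0.36), glycolysis (0.95), endoplasmic reticulum stress (0.25), heat shock and immediate early genes (0.42), the circadian clock (0.59) and oxidative stress and detoxification (0.95). Klf4, a transcription factor of differentiating epithelia, was 0.65 higher on the log2 scale and was the only immediate early gene past the threshold adjusted over the list alone (limma adjusted p over all genes = 0.44, 0.019 without pool 1 and 0.019 to 0.98 over all alternatives). Immune and stromal lists were not called either: interferon response (adjusted p = 0.42), MHC class II and dendritic cell (0.81), macrophage and neutrophil (0.59), T and NK cell (0.91), mast cell and eosinophil (0.59), fibroblast and matrix (0.95), smooth muscle (0.81), endothelium (0.69) and enteric neuron and glia (0.81). The antrum and duodenum list was not called (adjusted p = 0.36), and Gast, the gastrin of antral G cells, had 664.9 against 822.9 ± 296 (SD, n = 3). Median, mean and camera direction differed in sign for the lists of somatostatin receptors, EGF family, glycolysis, circadian clock, oxidative stress, interferon response, T and NK cell, mast cell and eosinophil, and enteric neuron and glia, none of them called.

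The remaining genes named by the fixed rule belonged to none of these lists' called groups. Abca3, a lipid transporter, had 1572 against 859.5 ± 95.1 (SD, n = 3), Snhg11, a noncoding host transcript, 593 against 278.3 ± 63.3 (SD, n = 3), Tmem230 1853 against 1146 ± 143 (SD, n = 3) and Kyat1 968.6 against 570.3 ± 58.6 (SD, n = 3). Nfia, a transcription factor, had 327.7 against 836.1 ± 181 (SD, n = 3), and its second probe set was lower, by -0.24 on the log2 scale. None of these passed with all chips. Nfia passed without pool 1, 2 or 3 (limma adjusted p = 5.92e-06, 0.0018 and 0.015; up to 0.9997 over all alternatives), Abca3 without pools 1 and 2 (0.042 and 0.011; up to 0.84) and Snhg11 without pool 2 (0.028; up to 0.95). In total, 11 named genes passed whichever treated pool was left out but not with all chips.

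**Figure D2:**
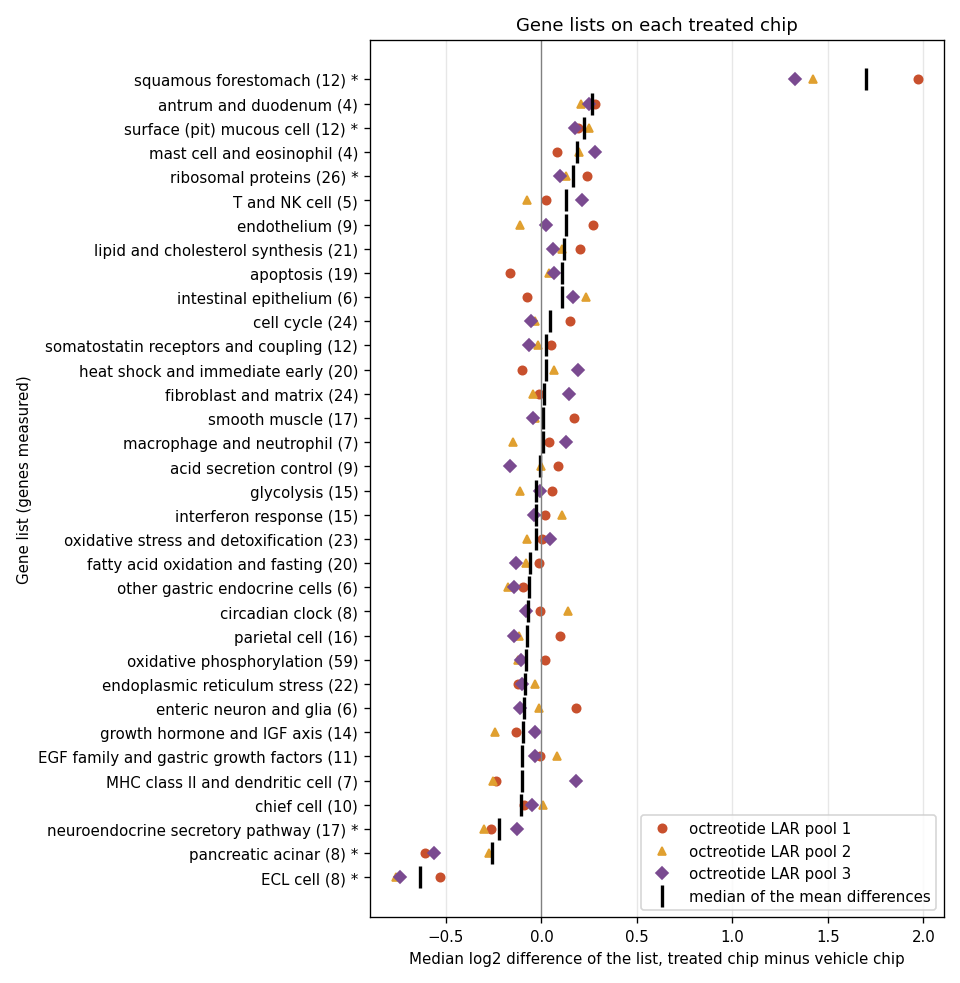
Median log2 difference of each gene list on each of the 3 octreotide LAR chips against the vehicle chip (horizontal axis), with the number of genes measured in brackets and an asterisk for the 6 lists called by camera; the bar is the median over genes of their mean differences. The squamous list lay at 1.33 to 1.97 and the ECL list at -0.76 to -0.53, while most other lists lay near 0.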

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

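All alternatives were planned before the data were examined. No paired analysis was possible because the vehicle group has 1 chip and shares only replicate number 1 with the treated group. Ratios of 3' to 5' signal of control probe sets were planned and not computed, since the control probe sets were not analysed here, so RNA quality was not compared between chips. Without detection calls, dim signals cannot be told from background. Of the 10 calls, Hdc, Krt1, Krt10 and Loricrin were made under 9 of 11 alternatives and Ampd2 under 5. The count of genes called was 0 without the filter, 5 with quantile normalization, 5 with centring on the 75th percentile, 1 without a trend of the spread on the level, and 31 to 55 when a treated chip was left out. Unadjusted p under 0.05 numbered 664, 592 and 435 without pool 1, 2 and 3. The cause of these differences was not tested. Each fit without a treated pool keeps the same vehicle chip, so genes that passed in all of them have not been shown to be robust. Probe sets at least 2-fold apart on every treated chip numbered 19 with pseudocount 64, 342 without the filter (222 higher, 120 lower), 9 with the filter at the 60th percentile, 148 at 1.5-fold, and 40 to 54 when a treated chip was left out. Gene lists called numbered 0 with an estimated correlation and 0 with fry, 5 to 9 otherwise. No called gene or list changed direction, and 8 values of uncalled genes and 30 of uncalled lists did; the cause was not tested. Without the filter, the median log2 difference was -0.052 for somatostatin receptors, 0.028 for acid secretion control, -0.054 for apoptosis, 0.00083 for glycolysis, 0.024 for interferon response, -0.020 for mast cell and eosinophil and -0.031 for intestinal epithelium. With the filter at the 60th percentile it was -0.0073 for somatostatin receptors and 0.15 for the EGF family, and with quantile normalization -0.0089 for smooth muscle. With the mean of a gene's probe sets it was -0.046 for somatostatin receptors, -0.035 for apoptosis and 0.10 for MHC class II, where RT1-Ba was at 0.10. Leaving out a treated chip gave log2 differences of -0.082 to 0.058 for Atp4a, -0.12 to 0.060 for Pgc, -0.059 to 0.060 for Sst, -0.15 to 0.033 for Ghrl, -0.19 to 0.41 for Sstr2, -0.026 to 0.43 for Gast and -0.010 to 0.26 for Anpep. The list medians then ran from -0.024 to 0.027 for somatostatin receptors, -0.026 to 0.058 for acid secretion control, -0.056 to 0.0035 for the EGF family, -0.12 to 0.027 for glycolysis, -0.021 to 0.11 for heat shock, -0.088 to 0.048 for the circadian clock, -0.063 to 0.0050 for oxidative stress, -0.029 to 0.11 for interferon response, -0.25 to 0.13 for MHC class II, -0.053 to 0.087 for macrophage and neutrophil, -0.058 to 0.045 for fibroblast and matrix, -0.045 to 0.093 for smooth muscle, -0.13 to 0.021 for enteric neuron and glia, and -0.0069 to 0.24 for intestinal epithelium.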

Other observations

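The tests of squamous tissue, of pancreatic tissue and of the probe set count with another lone chip were chosen after their values were seen. The others were recorded as written before, but those on the ECL genes and on Fabp2 and Lgals4 name patterns already seen. Beyond the genes already described, 27 of the 31 probe sets at least 2-fold apart on every treated chip carry a gene name, and 7 of these are in the squamous list. The rest include Serpinb12, a serpin of epithelia, at 89.1 on the vehicle chip against 217.9, 218.5 and 221.2, Lynx1, a toxin-like receptor modulator, at 50 against 188.6, 196.6 and 268.2, and B3galt5, a glycosyltransferase of digestive epithelia, at 43 against 236.4, 247.5 and 212.9. Pygm, the muscle-type glycogen phosphorylase, had 79.5 against 295.4, 282.5 and 225.4. None of these 4 passed over all genes with all chips, although B3galt5 did without pool 1, 2 or 3 (limma adjusted p = 0.015, 0.0015 and 0.0069; 0.056 with all chips and up to 0.83 over all alternatives), and their vehicle signals lie under the level that the filter set for the mean. Nr1d1, a clock repressor, had 173.1 on the vehicle chip against 389.5 ± 135 (SD, n = 3), and its relative Nr1d2 had 350 against 499.5 ± 106 (SD, n = 3), neither past the threshold with all chips. Nr1d1 passed without pool 1 (limma adjusted p = 0.0056; 0.0056 to 0.9997 over all alternatives). Ctrb1, a chymotrypsinogen, had 3107 against 2450 ± 353 (SD, n = 3), also without passing.

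Taking each chip in turn as the lone chip called 10 probe sets for the vehicle chip and at most 4 for a treated chip, and 6 lists for the vehicle chip against at most 6 for a treated chip. The count for the vehicle chip was reached by 1 of 4 choices for probe sets and by 2 of 4 for lists, and 4 choices are too few for a share under 0.05.

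Hdc, Slc18a2, Chgb and Chga were lower by 0.80 to 1.59 on the log2 scale on the treated chips. Dilution of the glandular mucosa by other tissue would lower parietal genes alike. The parietal list's median log2 difference was 0.09, -0.12 and -0.14 on the 3 treated chips, the lowest being -0.14, above the bound of -0.3 set for it. Of its 16 measured genes, 4 were lower and 1 was higher on every treated chip, so a slight dilution is not excluded. A fall shared by all gastric endocrine cells would lower Sst and Ghrl, whose mean log2 difference was at its lowest -0.11, although the dimmer Cck and Gal were lower on all treated chips without passing. What stays open is whether the ECL cells were fewer, as an antitrophic effect of the analogue may bring, or held less of these transcripts; cell numbers were not measured, so the biological hypothesis of an ECL-restricted response was not tested further. An unusually high ECL share in the single vehicle pool stays open as well.

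Of the 12 measured squamous genes, 11 were higher on every treated chip. Forestomach tissue scraped along with the corpus may account for this, and with the filter off the median log2 difference over the 15 genes of the list was 1.63, 1.02 and 1.17, at its lowest 1.02. This reads the list that showed the pattern, so it does not bear on the explanation. Basal keratins (Krt5, Krt14, Krt15) and suprabasal ones (Krt1, Krt10) were higher together. A squamous programme induced in the corpus by the analogue and a vehicle pool with less forestomach edge than usual stay open as well, all untested.

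Some genes best known from neighbouring organs differed in opposite directions. Intestinal tissue in the treated pools would raise the intestinal list, whose median log2 difference over 18 genes without Fabp2 was at its highest 0.19 on a treated chip. Pancreatic tissue in the vehicle pool would lower the acinar list on the treated chips, whose median over 15 genes without Cela2a, Cel and Cpa1 was -0.11, 0.09 and -0.31, at its lowest -0.31. Only 5 of these genes in each list lay above the filter, and dim genes may hide a share of tissue, so both explanations stay open. The bound of 0.3 for the intestinal list was met, but that test names Fabp2 and Lgals4 as higher, so it followed their values. On the vehicle chip, 7 chosen pancreatic genes, among them Prss1, Prss2 and Pnlip, reached at most 182.2, while Clps had 48789. Some other acinar genes were brighter there than the chosen ones. Cel, Cela2a and Cpa1 had 729.9, 612.5 and 602.2, and Ctrb1, given above, was brighter still. On any chip, 6 chosen intestinal genes, among them Apoa1 and Alpi, reached at most 137.2. Levels of different probe sets are not directly comparable, so these values do not decide.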
